A study of Homo sapiens with 4 samples.

How the data were processed

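The series holds 4 mRNA sequencing libraries of human gingival fibroblasts, 2 given Sg SCS at 5% and 2 untreated, grouped by the treatment in the labels. Per the labels' protocols, total RNA was extracted after 24 h and 1 µg per sample entered a NEBNext Ultra library preparation with paired-end clustering. The authors deposited FPKM values, 1 value per gene and library, per the file headers. The submitters' processing notes name STAR, DESeq2 and the build hg38 without roles or versions; the counter and the annotation are not given in the sources used here, nor is the strand setting.

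All 26235 gene identifiers of each file were found in GENCODE 29, and 26035 had a symbol in a table of current gene names. Each deposited FPKM value multiplied by the gene's merged exon length in GENCODE 29 was a whole multiple of 1 step per library (100% of values, within 0.01 of a read), so whole read counts could be recovered. The totals were 17752551 and 23905377 reads for Sg SCS replicates 1 and 2, and 23691357 and 18166586 reads for control replicates 1 and 2. The divisors behind the values were proportional to median-of-ratios size factors rather than to each library's own total, so the values already carry a between-library normalization. A single read corresponded to 0.0411 to 0.0560 FPKM for a gene of 1 kb, and statements on genes with few reads cover counting error only.

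Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested (12132 genes, 10684 protein-coding and 235 of short RNA classes). Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Errors beside FPKM values are standard deviations of 2 libraries, and errors beside log2 fold changes are limma standard errors. Values were not rescaled further, and the recovered reads entered only an alternative test with voom.

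Gene lists were fixed before the data were examined: 39 lists with 1019 distinct genes on inflammation, matrix, stress, metabolism, cell cycle and markers of other cell types. Each list with at least 5 tested members (37 lists) was tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Genes named in the text followed a rule set at the same time: up to 15 per direction, which pass or else have the smallest p, with a mean of at least 2 FPKM in the higher group, no overlap between the groups and a gene symbol, leaving out predicted loci, antisense genes, pseudogenes and sex-linked marker genes; up to 4 members of each list by smallest p; and 18 inflammatory, matrix and NRF2 genes. Members of the interferon list named in the closing section were chosen after their values were seen.

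GC content and length came from GENCODE 29 and were available for 99.97% of the tested genes. In a correction for them, chosen after the data were seen, splines with 5 degrees of freedom of GC content and of log2 length were fitted to each library's deviation from the mean of the 4 libraries and subtracted. Tests were run first on simulated data. For this comparison over 12132 genes, 31 of 50 genes changed 2-fold (62%) and 44 of 50 changed 4-fold (88%) were recovered, against 6 of 50 at 1.5-fold (12%) and 1 of 50 at 1.25-fold, with 7 unchanged genes called. A simulated list shifted by 0.15 was recovered and 0 other lists were called. The simulated genes varied independently of each other, so this does not show how camera behaves where genes move together within a library.

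The alternatives were other pseudocounts (0.1 and 0.5), no filter and a filter at 5 FPKM, rescaling to a common sum, median-of-ratios factors over the tested genes, quantile normalization, eBayes without the trend or with robust settings, a 1.5-fold minimum, the replicate number as a block, and each library left out. Added after seeing the data were the GC and length correction alone, with the block and without Sg SCS replicate 2, protein-coding genes only, voom, and a block with crossed replicate numbers. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.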

Results

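Gene expression was measured by mRNA sequencing in human gingival fibroblasts, the connective-tissue cells of the gum, labelled as the line HGF-1. The titles of the control samples alone also call their cells primary, so a difference in cell source between the groups is not excluded by the labels. Cells given Sg SCS at 5% (2 libraries) were compared with untreated cells (2 libraries), and RNA was taken after 24 h. Sg SCS was collected from cultures of the oral bacterium Sg grown in DMEM, and the study also tested it for an effect on proinflammatory cytokine expression in several human cell types after stimulation with Pg-LPS. The labels do not say whether these 4 cultures received Pg-LPS, nor whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Each library listed 26235 genes. The read counts behind the FPKM values summed to 17752551 for Sg SCS replicate 1, 23905377 for Sg SCS replicate 2, 23691357 for control replicate 1 and 18166586 for control replicate 2. The log2 values of any pair of libraries correlated at a Pearson r of 0.985 to 0.991 across genes, which are not independent replicates. The Sg SCS libraries correlated less with each other (0.987) than Sg SCS replicate 1 did with either control (0.991 each), and the controls correlated at 0.991.

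The comparison of Sg SCS with control addressed gene expression in fibroblasts given the bacterial product. Mitosis genes as a group lay lower in the cells given Sg SCS (median log2 fold change −0.13 over 42 genes). Targets of NRF2, the transcription factor of the oxidative stress response, lay higher (0.16 over 33 genes), as did the mitochondrially encoded mRNAs (0.18 over 13 genes). Genes of antigen presentation (0.15 over 12 genes) and of collagen processing and crosslinking (0.12 over 22 genes) lay higher as well. These last lists are rich in GC, and neither passed with GC content and gene length corrected (camera adjusted p = 0.251 and 0.221). These 5 of 37 gene lists fixed in advance passed limma's camera test with a preset inter-gene correlation, and none of the 5 passed with an estimated correlation, where the adjusted p of each was 0.950, nor by limma's fry test, where it was 0.841. An inter-gene correlation estimated from 4 libraries leaves the test little power, so failing it does not show that a list stayed in place. The preset value may in turn be too low for genes that move together within a library. No single gene passed.

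Of 12132 genes tested with limma on log2(FPKM + 1), 0 reached an adjusted p of 0.05, and the lowest adjusted p was 0.208. At an unadjusted p of 0.05 there were 653 genes, 354 with a higher and 299 with a lower value in Sg SCS, where chance alone gives 607. The voom test of limma on the recovered reads gave 0 genes with a lowest adjusted p of 0.106, and 879 at the unadjusted level. The unadjusted limma count was 3242 without Sg SCS replicate 1, 321 without control replicate 1 and 324 without control replicate 2. The log2 fold changes were small: 95% of them lay between −0.32 and 0.29, with a median standard error of 0.11. The groups did not overlap for 40.8% of the genes, against 33.3% expected by chance with 2 libraries each. Without control replicate 1, 20 genes passed (14 higher and 6 lower), and without control replicate 2, 4 genes passed (1 higher and 3 lower). These were short RNA genes, pseudogenes, antisense transcripts and other non-coding or gene-segment entries, and 0 were protein-coding.

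Under the rule for named genes, those with the smallest p on the higher side, none of which passed, were mostly protein-coding (13 of 15). MRPS18A (ENSG00000096080; GRCh38 chromosome 6, 43671303 to 43687791), a protein of the mitochondrial ribosome, had 11.2 and 10.8 FPKM in the Sg SCS libraries and 7.91 and 7.93 FPKM in the controls, a log2 fold change of 0.43 ± 0.08 (SE; limma adjusted p = 0.633). MRPL12, another protein of that ribosome, had a log2 fold change of 0.38 ± 0.09. The zinc finger genes ZNF358 and ZNF579 were at 0.49 ± 0.10 and 0.38 ± 0.09, and the Polycomb group gene PCGF2 at 0.38 ± 0.08. SFRP2, a secreted modulator of WNT signalling, was measured at 27.5 ± 1.48 FPKM with Sg SCS and at 21.3 ± 0.140 FPKM without (SD, n = 2 each). H1-10, a linker histone, was measured at 44.6 ± 0.954 and 34.8 ± 1.80 FPKM. INKA1, SELENOO, ALKBH5, the RNA demethylase, WDR18, FGD1 and the homeobox gene HLX completed the protein-coding genes, with log2 fold changes of 0.33 to 0.42. The limma adjusted p of these genes other than MRPS18A was 0.740. The GC content of the 13 protein-coding genes ran from 51.4% in SFRP2 to 68.6% in H1-10, and protein-coding genes of the highest eighth by GC content had a median log2 fold change of 0.14 as a whole.

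On the lower side, 13 of the 15 genes named by that rule were short RNA genes, most of them with few reads. MIR4730, the gene of smallest p among those with a mean of at least 2 FPKM in the higher group, rested on 2 and 3 reads with Sg SCS and on 9 and 6 reads in the controls (log2 fold change −1.12 ± 0.11; limma adjusted p = 0.208). SNORD114-1 had 2 and 2 reads against 10 and 12, and SNORD116-24 had 5 and 3 against 16 and 14. The limma errors come from the spread between libraries, and a choice by smallest p favours genes whose libraries lie close together. Such an error can lie below the counting error, most of all at so few reads. The better counted members were 7SL RNA genes, which encode the RNA of the signal recognition particle. RN7SL2 (ENSG00000274012; GRCh38 chromosome 14, 49862550 to 49862849) had 234 and 197 FPKM with Sg SCS and 327 and 361 FPKM in the controls, a log2 fold change of −0.68 ± 0.12 (limma adjusted p = 0.632). RN7SL3 had 7.60 ± 0.113 against 13.5 ± 0.175 FPKM (−0.75 ± 0.08; limma adjusted p = 0.255). These 7SL genes are near-identical copies, and many short RNA genes lie inside longer genes, so their reads cannot be assigned with certainty. PDF, a mitochondrial peptide deformylase, was the protein-coding gene of this side, with 4.34 ± 0.452 against 6.39 ± 0.194 FPKM (−0.47 ± 0.10; limma adjusted p = 0.740).

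The mitosis list, genes of chromosome segregation and cell division, shifted down as a set (camera adjusted p = 2.91e-05; adjusted p = 0.950 with an estimated correlation). Of its 42 members, 34 had a lower and 8 a higher point estimate. In 27 members both Sg SCS libraries lay below both controls, and in 3 both lay above. No member passed the test over all genes or adjusted over the list alone, where the lowest value was 0.255. MKI67, the proliferation marker, was at 12.2 ± 2.61 FPKM with Sg SCS and at 15.9 ± 0.784 FPKM in control, a log2 fold change of −0.37 ± 0.14. TTK, a spindle checkpoint kinase, was at −0.38 ± 0.11, the kinetochore motor CENPE at −0.37 ± 0.14 and DLGAP5 at −0.21 ± 0.08, each with a limma adjusted p of 0.740. The median GC content of the 42 members was 44.6%, with MKI67 at 48.0%, TTK at 38.8%, CENPE at 35.5% and DLGAP5 at 38.3%. With each library corrected for GC content and gene length the list's median was −0.12 (camera adjusted p = 8.51e-07, and 0.977 with an estimated correlation). The corrected median was −0.06 without Sg SCS replicate 2 and −0.07 without control replicate 2. Genes of S phase had a median of −0.02 over 31 members (camera adjusted p = 0.517).

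NRF2 targets shifted up as a set (camera adjusted p = 9.95e-05; adjusted p = 0.950 with an estimated correlation), with 30 of 33 members higher and 3 lower by point estimate. In 14 members both Sg SCS libraries lay above both controls, and in 0 both lay below. No member passed over all genes or adjusted over the list alone, where the lowest value was 0.263. EPHX1, a microsomal epoxide hydrolase, was at 40.1 ± 5.47 against 30.2 ± 0.250 FPKM (log2 fold change 0.39 ± 0.11). The aldo-keto reductase AKR1B10 was at 0.46 ± 0.14 and OSGIN1 at 0.26 ± 0.10. The classical targets NQO1 and HMOX1 were at 0.17 ± 0.09 and 0.22 ± 0.15, with limma adjusted p = 0.740 for each of the 5 genes. The displacement lay mainly in Sg SCS replicate 2, where the members' median was 0.22 above the mean of the 4 libraries, against 0.02 in Sg SCS replicate 1, −0.05 in control replicate 1 and −0.08 in control replicate 2. Without Sg SCS replicate 2 the median was 0.07 (camera adjusted p = 0.0707), and without Sg SCS replicate 1 it was 0.26 (camera adjusted p = 1.54e-05). The members had a median GC content of 49.9%, and with the GC and length correction the median fold change was 0.12 (camera adjusted p = 2.84e-06; adjusted p = 0.977 with an estimated correlation).

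The 13 mitochondrially encoded mRNAs, subunits of the respiratory chain and ATP synthase, shifted up as a set (camera adjusted p = 0.00144; adjusted p = 0.950 with an estimated correlation). A higher point estimate was found in 12, a lower one in 1, and in 8 both Sg SCS libraries lay above both controls. No member passed over all genes or adjusted over the list alone, where the lowest value was 0.467. MT-CO2 had a log2 fold change of 0.30 ± 0.17, MT-ND1 of 0.22 ± 0.13, MT-CYB of 0.21 ± 0.13 and MT-ND2 of 0.19 ± 0.13, each with a limma adjusted p of 0.740. The median was 0.24 with the GC and length correction (camera adjusted p = 2.74e-09; adjusted p = 0.977 with an estimated correlation). It was 0.12 without control replicate 1 (camera adjusted p = 0.134) and 0.00 after quantile normalization, where the list no longer passed (camera adjusted p = 0.941). Reads from the mitochondrial genome made up 3.87% and 4.32% of the Sg SCS libraries and 3.67% and 3.78% of the controls. The nuclear-encoded respiratory chain genes had a median of 0.02 over 50 members (camera adjusted p = 0.517), with COX5A at 0.29 ± 0.10. Their median was 0.18 without Sg SCS replicate 1 (camera adjusted p = 4.51e-06) and −0.12 without Sg SCS replicate 2 (camera adjusted p = 1.38e-05).

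Antigen presentation genes shifted up (camera adjusted p = 0.0156; adjusted p = 0.950 with an estimated correlation), with 10 of 12 members higher by point estimate. HLA-DPB1 was at 0.30 ± 0.10, the immunoproteasome subunit PSMB10 at 0.33 ± 0.11, TAPBP at 0.18 ± 0.08 and HLA-C at 0.20 ± 0.14; HLA genes share sequence, so their reads can be split between relatives. Collagen processing genes shifted up as well (camera adjusted p = 0.0156; adjusted p = 0.950 with an estimated correlation), with 17 of 22 members higher by point estimate. LOXL1, a lysyl oxidase that crosslinks elastin and collagen, was at 65.9 ± 4.35 against 54.6 ± 2.14 FPKM (0.26 ± 0.09), and the procollagen proteinase enhancers PCOLCE and PCOLCE2 were at 0.26 ± 0.13 and 0.17 ± 0.08. No member of either list passed over all genes or adjusted over the list alone, where the lowest values were 0.162 and 0.390. Both lists are rich in GC (median 58.1% and 57.6%), and with the GC and length correction their medians were 0.07 (camera adjusted p = 0.251) and 0.05 (camera adjusted p = 0.221). Neither list passed after quantile normalization (camera adjusted p = 0.0911 and 0.189). Without Sg SCS replicate 2 the medians were 0.01 (camera adjusted p = 0.666) and 0.06 (camera adjusted p = 0.0707). Antigen presentation was at 0.25 without Sg SCS replicate 1 (camera adjusted p = 0.00154) and was also lost without control replicate 2 (0.13; camera adjusted p = 0.202), and collagen processing without control replicate 1 (0.10; camera adjusted p = 0.191).

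**Figure D1:**
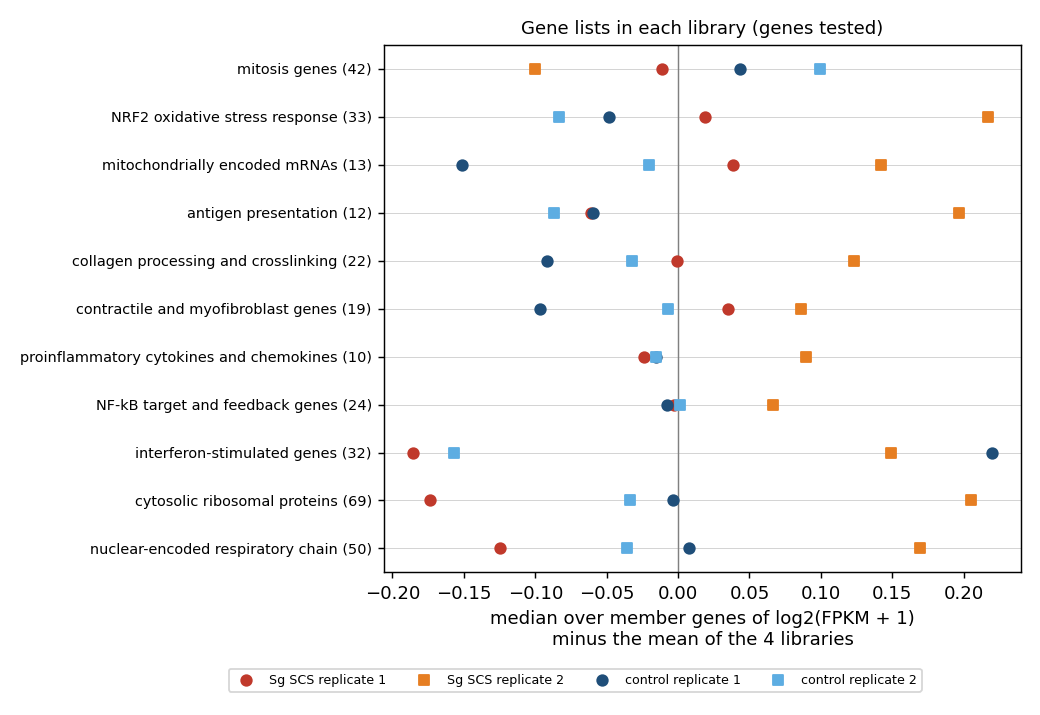
Median over the members of 11 gene lists of log2(FPKM + 1) in each library minus the mean of the 4 libraries, with the number of genes tested in brackets and 1 point per library. Sg SCS replicate 2 lies farthest from the other libraries for the NRF2 list (0.22), while the interferon-stimulated genes separate Sg SCS replicate 2 and control replicate 1 from the other libraries.

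Fold changes ran along the GC content of the genes, and the libraries of one group differed along it too. Across 10680 protein-coding genes with a GC value, which are not independent replicates, the Spearman correlation of the fold change with GC content was 0.71. It was 0.53 for the difference between the Sg SCS replicates and 0.25 for that between the controls. The correlation of the fold change was 0.37 without Sg SCS replicate 2, 0.71 without Sg SCS replicate 1, 0.58 without control replicate 1 and 0.71 without control replicate 2. Protein-coding genes of the lowest eighth by GC content (32.0% to 40.3%) had a median log2 fold change of −0.15, and those of the highest (60.8% to 74.2%) one of 0.14. Some genes named below with opposite fold changes also differ in GC content along this trend. These are TGFB1 (61.4%) and TGFB2 (38.9%), BGN (61.0%) and VCAN (43.6%), RELA (60.3%) and TRAF6 (43.2%), and FTH1 (53.9%) and TFRC (41.8%). Their fold changes are given without the correction. Per 10 percentage points of GC, the deviation of the log2 value from the mean of the 4 libraries changed by 0.12 in Sg SCS replicate 2, −0.01 in Sg SCS replicate 1, −0.07 in control replicate 1 and −0.04 in control replicate 2. These slopes are relative to that mean and balance each other, so they are not each library's own trend.

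**Figure D2:**
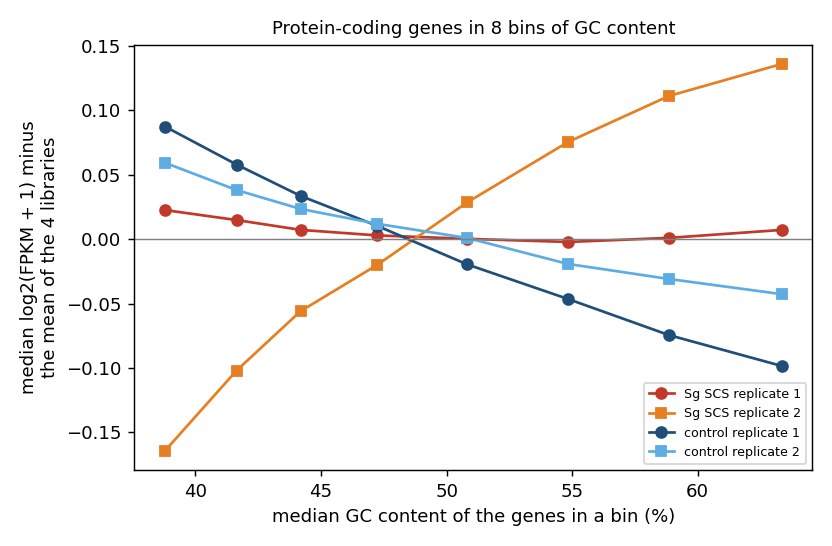
Median log2(FPKM + 1) of protein-coding genes minus the mean of the 4 libraries, in 8 bins of GC content, with 1 line per library. The line of Sg SCS replicate 2 rises from −0.16 in the lowest bin to 0.14 in the highest, and that of control replicate 1 goes from 0.09 to −0.10.

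Inflammatory genes showed no detectable difference. The study's cytokine tests followed stimulation with Pg-LPS, which the labels do not give for these cultures, so the results are not comparable. In simulated data 6 of 50 genes changed 1.5-fold were recovered, so a modest change would mostly be missed. IL6, a proinflammatory cytokine, stayed below the expression filter in every library (0.623 and 0.595 FPKM with Sg SCS, 0.656 and 0.767 FPKM in control). IL1B was counted with 1 to 3 reads per library, which allows no comparison, and TNF had no entry under its symbol among the deposited genes. CXCL8, a neutrophil chemokine, was at 3.24 ± 0.647 against 2.89 ± 0.237 FPKM (log2 fold change 0.12 ± 0.13; limma adjusted p = 0.808). The monocyte chemokine CCL2 was at −0.14 ± 0.16 (limma adjusted p = 0.816) and CXCL1 at 0.12 ± 0.18 (limma adjusted p = 0.862). The proinflammatory list had a median of 0.10 over 10 tested members (camera adjusted p = 0.517), among them CSF1 at 0.17 ± 0.09, CXCL5 at −0.20 ± 0.11 and IL11 at 0.12 ± 0.09. NF-kB targets had a median of 0.02 over 24 members (camera adjusted p = 0.515). NFKBIA, the inhibitor that NF-kB induces, was at 0.15 ± 0.10, TNIP1 at 0.20 ± 0.08 and NFKB2 at 0.20 ± 0.09. In the Toll-like and NOD receptor list (median 0.02 over 18 members; camera adjusted p = 0.853), MYD88 was at 0.01 ± 0.10, RELA at 0.21 ± 0.08 and TRAF6 at −0.21 ± 0.10, while TLR2 and TLR4 were below the filter with at most 0.334 and 0.338 FPKM. No member of these lists passed over all genes or adjusted over the list alone. Complement genes (median −0.02 over 9 members; camera adjusted p = 0.891) and inflammasome and cell death genes (0.00 over 16 members; camera adjusted p = 0.761) were not shifted either.

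**Figure D3:**
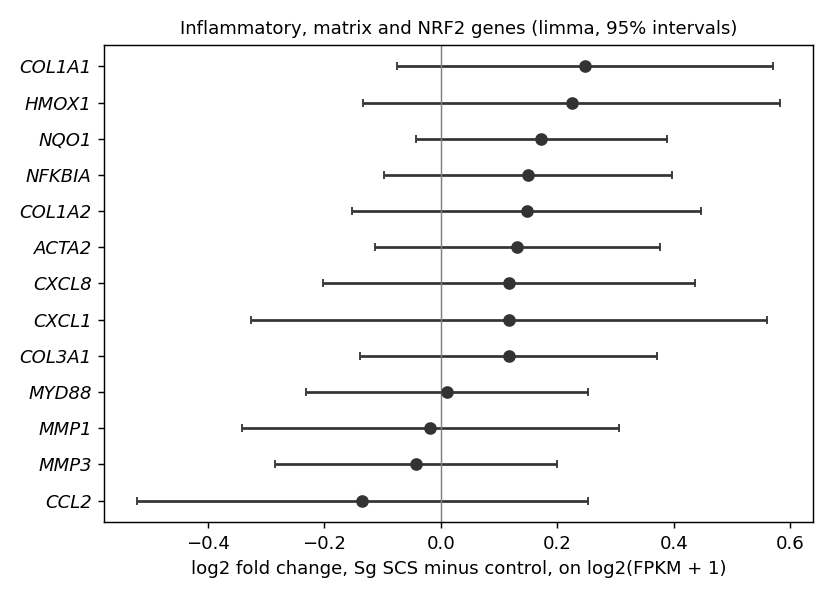
Log2 fold change of Sg SCS against control on log2(FPKM + 1) for 13 inflammatory, matrix and NRF2 genes chosen in advance, with points for the limma estimate and bars for its 95% interval (2 libraries per group). Every interval includes 0, from COL1A1 at 0.25 to CCL2 at −0.14.

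The genes of type I and type III collagen were abundant, while some matrix protease genes, such as MMP9, lay below the expression filter. COL1A1, the main chain of type I collagen, had 1.19 times the control's mean FPKM (log2 fold change 0.25 ± 0.13; limma adjusted p = 0.740), COL1A2 was at 0.15 ± 0.12 and COL3A1 at 0.12 ± 0.11. The fibrillar and basement membrane list had a median of −0.02 over 45 members while its camera direction was up (camera adjusted p = 0.925), with the proteoglycans BGN at 0.27 ± 0.09 and VCAN at −0.28 ± 0.11. The collagenase MMP1 was at −0.02 ± 0.13, the stromelysin MMP3 at −0.04 ± 0.10, MMP14 at 0.15 ± 0.12 and MMP16 at −0.28 ± 0.13, within a list of matrix proteases and inhibitors whose median was 0.06 over 25 members (camera adjusted p = 0.515). Contractile and myofibroblast genes had a median of 0.13 over 19 members (camera adjusted p = 0.0651), which was 0.19 without control replicate 2 (camera adjusted p = 0.0257), with ACTA2, smooth muscle actin, at 0.13 ± 0.10, LMOD1 at 0.29 ± 0.09 and TPM2 at 0.19 ± 0.11. TGF-beta response genes had a median of 0.06 over 23 members (camera adjusted p = 0.491); TGFB1 was at 0.30 ± 0.10 and TGFB2 at −0.25 ± 0.12. Without control replicate 2 the median of the TGF-beta response list was 0.14 (camera adjusted p = 0.0343). No member of these lists passed over all genes or adjusted over the list alone.

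Further lists of stress responses and metabolism did not pass. The median log2 fold change was 0.05 for ATF4 targets (31 genes), 0.01 for endoplasmic reticulum chaperones (24 genes), 0.05 for cytosolic heat shock genes (19 genes), −0.01 for p53 targets (23 genes) and −0.07 for hypoxia genes (24 genes). It was 0.05 for glycolysis (22 genes), 0.09 for autophagy and lysosome (25 genes), 0.04 for cholesterol synthesis (25 genes) and −0.01 for fatty acid synthesis (13 genes). The lowest camera adjusted p among these lists was 0.167, for glycolysis and for autophagy and lysosome. Without Sg SCS replicate 1, 3 of these lists passed: glycolysis (0.12; camera adjusted p = 0.0392), autophagy and lysosome (0.18; camera adjusted p = 0.00325) and ATF4 amino acid response (0.17; camera adjusted p = 0.00841). HSPA1A, a heat shock protein whose near-identical copy can take part of its reads, was at 0.32 ± 0.11. The lysosomal protease CTSD was at 0.33 ± 0.13, the glucose transporter SLC2A3 at −0.25 ± 0.08 and GPI at 0.22 ± 0.08. Ferritin heavy chain FTH1 was at 0.37 ± 0.18, the transferrin receptor TFRC at −0.20 ± 0.10 and IREB2 at −0.28 ± 0.13 in an iron list with a median of −0.01 over 9 members (camera adjusted p = 0.891). JUND was at 0.27 ± 0.08 and IER2 at 0.29 ± 0.09 among the immediate early genes (median 0.04 over 22 members; camera adjusted p = 0.517). The limma adjusted p of these 9 genes was 0.740, and no member of these lists passed over all genes or adjusted over the list alone.

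The interferon-stimulated genes had a median of −0.05 over 32 members between the groups (camera adjusted p = 0.640), but differed between libraries within both groups. Relative to the mean of the 4 libraries their median was 0.15 in Sg SCS replicate 2 and 0.22 in control replicate 1, against −0.19 in Sg SCS replicate 1 and −0.16 in control replicate 2. The direction between the groups turned with the library left out: the median was 0.15 without control replicate 1 (camera adjusted p = 0.000117), −0.23 without control replicate 2 (camera adjusted p = 5.25e-07) and −0.20 without Sg SCS replicate 2 (camera adjusted p = 0.00162). Cytosolic ribosomal protein genes had a median of 0.03 over 69 members (camera adjusted p = 0.517). Sg SCS replicate 1 was at −0.17 and Sg SCS replicate 2 at 0.20 for this list, with the controls between them, and the median was 0.22 without Sg SCS replicate 1 (camera adjusted p = 2.76e-12) and −0.16 without Sg SCS replicate 2 (camera adjusted p = 2.47e-15). No member of either list passed over all genes or adjusted over the list alone.

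Markers of other cell types were low, or formed lists that did not pass. None of the 20 leukocyte and macrophage markers passed the filter, and the highest value of any was 0.456 FPKM, for CORO1A. Of 18 endothelial markers 4 passed, led by EGFL7 with at most 8.30 FPKM and a log2 fold change of 0.26 ± 0.15; neither list had enough tested members for a set test. Epithelial markers had a median of 0.13 over 5 tested members (camera adjusted p = 0.405); KRT18 was at 0.24 ± 0.09, the desmosomal protein DSP at −0.23 ± 0.12 and KRT19 at 0.26 ± 0.14. Pericyte, muscle and glia markers had a median of 0.00 over 7 members (camera adjusted p = 0.745). Gingival fibroblast identity genes were at 0.12 over 19 members (camera adjusted p = 0.213), with ENG at 0.24 ± 0.09, PITX1 at 0.26 ± 0.11 and VIM at 0.20 ± 0.11. No tested member of these lists passed over all genes, and none of the epithelial, pericyte or fibroblast identity members passed adjusted over the list alone, where the lowest value was 0.145.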

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

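The GC and length correction, the restriction to protein-coding genes, voom and the crossed block were chosen after the data were seen; the other 17 settings were fixed before. The number of genes changed by Sg SCS stayed at 0 in all settings but 4: it was 1 gene, 1 of the genes lower in Sg SCS, in eBayes without the trend, it ranged from 0 to 20 with single libraries left out (genes higher in Sg SCS 0 to 14, lower 0 to 6), and it was 44 with a crossed replicate block (12 higher and 32 lower). In fits without 1 library the lone sample of its group is assumed to vary like the other group. The cause was not tested. Deviations of same-numbered libraries correlated at −0.04 across genes (−0.10 with GC and length corrected), which gives no sign that the replicate numbers pair the libraries. A state shared by some gene lists, as between the deeper libraries, hardly moves this measure, so a pairing is not excluded. A block on the replicate number left 0 genes and 5 gene lists shifted as a set. The crossed block with GC and length corrected gave 0 genes and 3 lists. Members of gene lists changed numbered 0 in every setting run.

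The count of gene lists shifted as a set, 5 as reported, was 0 with an estimated correlation and 0 by fry, 2 after quantile normalization, 3 with the GC and length correction, alone or with the replicate block, and 4 to 10 with single libraries left out. That count was 4 with a filter of 5 FPKM, and 6 with no filter, with protein-coding genes only and with voom. With an estimated correlation and by fry the medians were as reported (mitosis genes −0.13, NRF2 oxidative stress response 0.16, mitochondrially encoded mRNAs 0.18, antigen presentation 0.15, collagen processing and crosslinking 0.12) and no list passed. Antigen presentation no longer passed at a filter of 5 FPKM (0.16), which tested fewer genes, after quantile normalization (0.12) or with the GC and length correction (0.067, and −0.027 also without Sg SCS replicate 2). Collagen processing and crosslinking no longer passed after quantile normalization (0.10) or with the GC and length correction (0.054, and 0.027 also without Sg SCS replicate 2). Mitochondrially encoded mRNAs were at 0.00 after quantile normalization, which gives the top ranks of every library the same values. With single libraries left out, medians ranged from 0.071 to 0.26 for the NRF2 list, 0.12 to 0.25 for mitochondrially encoded mRNAs, 0.011 to 0.25 for antigen presentation and 0.062 to 0.17 for collagen processing; mitosis genes passed in each of these fits (−0.19 to −0.10). The lists that reversed did so with single libraries left out: interferon-stimulated genes ranged from −0.23 to 0.15, cytosolic ribosomal proteins from −0.16 to 0.22 and the nuclear-encoded respiratory chain from −0.12 to 0.18. The latter lists were at −0.15 and −0.095 without Sg SCS replicate 2 and with GC and length corrected. Rescaling to a common sum moved the median of all genes to −0.07 and the 5 medians to −0.21, 0.09, 0.11, 0.09 and 0.06, with each list still past the threshold. The cause of the other losses was not tested. Of 191 named genes, 15 passed in at least 1 setting, each a short RNA gene or gene segment, and 29 had a point estimate that turned sign in at least 1 setting without passing. Depth limits the short RNA genes most, several of which rest on fewer than 10 reads per library.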

Other observations

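The tests of the splits, of single libraries, of GC content and of the correction for it were chosen after the results they bear on were seen, while the camera tests of the lists between the groups and the tests of sampling noise and of library depth were set before their results.

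Further lists fixed in advance did not pass between the groups. Growth factors and wound repair genes had a median log2 fold change of −0.07 over 23 members (camera adjusted p = 0.640), with HGF, the hepatocyte growth factor, at −0.25 ± 0.10 (SE). Osteogenic and periodontal genes were at −0.01 over 13 members (camera adjusted p = 0.965), with the periodontal ligament gene ASPN at −0.32 ± 0.10 and the tendon transcription factor SCX at 0.31 ± 0.13. Glucocorticoid targets were at 0.07 over 11 members (camera adjusted p = 0.568), metallothioneins and zinc transport genes at −0.06 over 7 (camera adjusted p = 0.745), and MondoA targets at −0.07 over 7 (camera adjusted p = 0.878). No member of these lists passed over all genes or adjusted over the list alone.

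The interferon-stimulated genes gave the lowest camera p of any list over the 3 splits of the libraries into pairs, in a split that does not follow the treatment. MX1, an antiviral GTPase, had 1.56 and 3.87 FPKM in Sg SCS replicates 1 and 2 and 4.47 and 1.45 FPKM in control replicates 1 and 2. IFIT1 had 2.17 and 5.35 FPKM with Sg SCS and 7.82 and 1.93 FPKM in control, IFIT3 had 8.51 and 14.9 FPKM with Sg SCS and 17.1 and 9.06 FPKM in control, and IFI6 had 34.5 and 58.4 FPKM with Sg SCS and 49.5 and 31.1 FPKM in control. These 4 genes were picked after their values were seen. In 25 of 32 tested members both deeper libraries (Sg SCS replicate 2 and control replicate 1) lay above both shallower ones, and in 0 both lay below. No member passed limma between these pairs (lowest adjusted p = 0.184).

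For this interferon pattern, the median difference between the deeper and the shallower pair was 0.32 (camera adjusted p = 2.28e-27, preset correlation). The pattern was picked as a difference that crosses the groups, whose own median was −0.05. Both pairs hold an Sg SCS and a control library, so a treatment effect common to both Sg SCS libraries cancels in this difference and cannot be its source. With every library thinned to the same total, 106% of the difference was kept (95% bootstrap interval over genes 60.9% to 164%). Thinning leaves each gene's expected value as it was, so little change was likely whatever the source. It speaks only to reads lost by sampling and does not decide on a cause linked to depth. With GC and length corrected 112% of the difference was kept (70.2% to 150%). These intervals show the spread between genes, not the error of the share kept. What stays open is a state shared by Sg SCS replicate 2 and control replicate 1, such as the culture or the library preparation, which may also go with their depth; the labels give no batch, so this is a hypothesis that was not tested.

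The dependence of the fold changes on GC content may come from single libraries. Replicates of one treatment differed along GC content (Spearman rho 0.53 between the Sg SCS libraries), as a library-specific GC bias needs. Untreated controls differed along it as well (rho 0.25), which argues against the treatment as the whole source, though a contribution of the treatment stays open. Sg SCS replicate 2 alone is not the whole source, since without it the fold change still ran along GC content (rho 0.37, against 0.71 with all libraries). Sampling noise of poorly counted genes is argued against by a rho of 0.77 among 3635 genes with at least 1000 reads in every library.

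After the GC and length correction 75.6% of the NRF2 median, 88.3% of the mitosis median and 133% of the mitochondrial median were kept, with 95% bootstrap intervals over genes of 0.08 to 0.13, −0.13 to −0.08 and 0.23 to 0.28, so the trend is argued against as their whole source. A mild response to Sg SCS stays open as a hypothesis. These lists also moved in splits that do not follow the treatment. Between the deeper and the shallower libraries the corrected medians were 0.07 for NRF2, −0.07 for mitosis and −0.07 for the mitochondrial list. In the remaining split, replicates 2 against replicates 1, they were 0.03, −0.01 and 0.08. Of the antigen presentation and collagen processing medians 45.9% and 43.8% were kept (intervals 0.01 to 0.11 and −0.01 to 0.10). For each list 10000 random lists were drawn from genes of like expression and GC content. In 95% of them the median lay between 0.020 and 0.161 for antigen presentation and between 0.035 and 0.136 for collagen processing. The observed 0.146 and 0.124 lay inside, while the NRF2, mitosis and mitochondrial medians lay outside their ranges. These draws hold no spread between libraries. A response of the antigen presentation and collagen genes beyond a GC trend is not shown. It is not excluded either, since the correction leaves part of the shift. In the corrected fits without each library, every median of the first 3 lists kept its sign. Its bootstrap interval over genes excluded 0 each time. These intervals hold no spread between libraries. For the interferon list the corrected interval also excluded 0 (0.23 to 0.50) in a split that does not follow the treatment. The fits therefore cannot decide whether a single deviating library is the whole source. The size of the shifts depended on single libraries: the corrected mitosis median was −0.060 without Sg SCS replicate 2 and −0.065 without control replicate 2. The NRF2 median without Sg SCS replicate 2 was 0.071 uncorrected and 0.091 corrected. The mitochondrial median without control replicate 1 was 0.12 uncorrected and 0.17 corrected. The 3 possible splits of 4 libraries into pairs are too few for a share under 0.05: the treatment shifted 5 lists, the split of the deeper from the shallower libraries 13, which points to a structure of the samples, and the remaining split 2, so that 2 of the 3 splits, the treatment's own included, shifted at least 5; with GC and length corrected the counts were 3, 16 and 3, and no split shifted fewer lists than the treatment.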
